A study of Mus musculus with 4 samples.

How the data were processed

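The measurement was ATAC-seq, in which the Tn5 transposase cuts open chromatin and adds sequencing adapters, so that the number of fragments from a region tracks its accessibility. Per the labels' protocols, 50000 cells entered each library and the libraries were sequenced on an Illumina NextSeq500 instrument. The cells were mouse fibroblasts of 4 genotypes. A kidney fibroblast pair comprised cells with floxed Kindlin-2 alleles and cells without Kindlin-2, and a 3T3 embryo fibroblast pair comprised wild-type cells and cells without Rela.

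Per the submitters' processing notes, which name tools without their role or order, the reads were handled with FastQC, Trimmomatic 0.33, STAR 2.4.2a, Picard 1.136, MACS2, deepTools, DESeq2 and bedtools on the mouse build mm10. How reads were shifted for the Tn5 cut, how duplicates and mitochondrial reads were treated and how regions were called are not given in the sources used here. The authors deposited 1 table per knockout, with 1 value column per genotype, the position of each region and the gene assigned to it. The values are a score, a background-corrected signal normalized within its own table by the DESeq method and rounded to whole numbers, per the labels' name for each table, and are called normalized signal here. They are not counts of reads, and levels of the 2 tables were not set against each other. The distance from a region's centre to the nearest transcription start is in the deposited tables and was used as it stands. The study's design text gives 2 biological replicates per genotype, and how they were combined into 1 column is not stated. Coordinates are those of the tables, on mm10; the tables do not state whether starts count from 0 or from 1.

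With 1 value per genotype, no test between genotypes could be made, so no p-value is given for any region, gene or list, and the planned Fisher tests of promoter shares are given as shares and odds ratios alone. The planned limma and camera tests, which needed replicate columns, were replaced by the descriptions planned for this case. Each region's change is log2((knockout + 1)/(control + 1)), with a pseudocount of 1, which understates the change of weak regions. Regions entered when the mean of both columns was at least 1. A region was called higher or lower when its log2 ratio was at least 1 in size, a 2-fold difference. Promoter regions had their centre within 2500 bp of the start of the assigned gene.

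The precision that depth gives was worked out from the values themselves. A whole-number count multiplied by a fixed factor and then rounded leaves some whole values too rare or too frequent. The factor explaining most of this pattern was 1.36 for Kindlin-2 floxed, where it explained 95.4% of the deviance (the next best factor explained 28.3%), 0.683 for Rela wild type (91.8%, next best 25.2%) and 0.949 for the Rela knockout (87.4%, next best 56.9%). For the Kindlin-2 knockout no factor explained more than 20.0%. After these fits were seen, that column was given a factor of 1, the largest that a single scaled library could have while every low whole value occurred in it, so that its counts were not overstated. If the column blends separately scaled replicates, its depth is unknown. Counts implied by these factors gave exact (Clopper-Pearson) 95% intervals of the ratio of 2 values. A signal of 0 was given a floor of 3 counts per library, and "at least" marks a fold against that floor. This fold takes the other value as exact, so the lower limit of the exact interval, which counts the error of both values and is smaller, is given beside it. These intervals and bounds cover counting error only, not the difference between cultures or replicates. They take each background-corrected value as a scaled count, so any error of the background correction is left out. Intervals may thus be too narrow, above all for values near 0. In each comparison, 100 draws with equal levels in both genotypes and counting error alone were made, to show how many regions would then pass 2-fold.

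Genes were described in 23 lists of pathways and cell type markers, holding 599 genes, that were fixed before the data were examined. List genes were matched by symbol, and otherwise by an older symbol that belongs to 1 gene in a gene table of assembly GRCm38.p6, from which no coordinates were taken. For each list with at least 5 measured genes, the median of the genes' mean log2 ratios was placed among 10000 random lists of the same size matched on 20 levels of mean signal. This percentile describes these libraries and is no test of genotype. The named regions were also fixed by rule: every region of the knocked-out gene; the 10 regions with the highest and the 10 with the lowest log2 ratio, 1 per gene, among regions with a gene symbol and a mean at or above the table's median; and in each list up to 4 genes whose regions past 2-fold had the largest log2 ratio, promoters first. Regions chosen after their values were seen are said to be so where they appear.

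On simulated data, 200 regions of at least median signal were changed by a known fold among otherwise equal regions. In the Kindlin-2 table with its 5727 regions, 57% of 2-fold, 96.5% of 4-fold and 100% of 8-fold changes were called in the right direction, and 9.57% of unchanged regions passed 2-fold in the 2-fold run. In the Rela table with its 28445 regions these shares were 51%, 99% and 100%, and 2.63% of unchanged regions passed. Regions of the 2 tables were paired 1 to 1 when they overlapped by at least 1 bp. Alternatives were another pseudocount, filters, median-of-ratios, quantile and loess scaling (span 0.3), centring on chromosomes or on neighbouring regions, leaving out mitochondrial, Y and wide regions, another promoter distance and another overlap. Motifs in the regions were not analysed here, because they need the genome sequence. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.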

Results

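Chromatin accessibility was profiled by ATAC-seq in mouse fibroblasts lacking either of 2 proteins, each beside its own control. Kindlin-2, encoded by Fermt2, is an adaptor that binds integrin tails and is needed for integrin activation, and Rela encodes p65, a transcription-activating subunit of NF-kB. The 4 genotypes were Kindlin-2 floxed and Kindlin-2 knockout kidney fibroblasts, and Rela wild-type and Rela knockout 3T3 fibroblasts. Each genotype had 1 column of normalized signal, so no difference below has a replicate check, and intervals in brackets are 95% intervals for counting error alone. The Kindlin-2 table held 5727 regions and summed to 1655317 for floxed and 827408 for knockout cells. Of these sums, 91.8% and 86.2% lay in 2 mitochondrial regions, which left 134996 and 114217 of nuclear signal. The Rela table held 28445 regions, with sums of 1386832 for wild-type and 1458609 for knockout cells. The median region had a signal of 16 in both Kindlin-2 genotypes, and of 34 and 35 in Rela wild-type and knockout cells. A median region thus rested on about 11.8 implied counts in Kindlin-2 floxed cells and 49.8 in Rela wild-type cells.

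The first comparison asked how accessibility differs between fibroblasts without Kindlin-2 and their floxed counterparts. Among genes of integrin adhesion, the promoter of Fermt1, which encodes the related adaptor kindlin-1, was 7-fold higher in the knockout (signal 4 and 28, interval 2.12 to 35.3). Those of the integrin gene Itgb8 and of the actin crosslinker Actn1 were 3.1-fold (1.41 to 8.76) and 2.63-fold higher (1.004 to 7.79). Once chromosomes were centred, both were within 2-fold, Itgb8 only just (log2 ratio 0.993). The other 7 of 10 measured genes were within 2-fold as deposited. Promoters of Nt5e, which encodes the ecto-enzyme CD73, and of the tissue factor gene F3, both YAP and TEAD targets, were 4.88-fold (2.20 to 12.5) and 2.68-fold lower (1.62 to 4.51). Over all regions, 925 of 5727 were at least 2-fold higher in the knockout and 531 were at least 2-fold lower. No region of the table was assigned to Fermt2, so the targeted gene could not be checked in these values.

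Among regions with a gene symbol and at least median signal, those most elevated in the knockout were led by the promoter of the kinesin gene Kif12, with a signal of 4 in floxed and 30 in knockout cells (log2 ratio 2.63). The Fermt1 promoter on chromosome 2 (132945422 to 132945929, 230 bp from the start) came next with 2.54, and its log2 ratio was 2.19 or more under each other scaling. Promoters of Fam172a, Hsdl2, Rassf6, Lancl2 and Bach1 had log2 ratios of 2.32, 2.22, 1.75, 1.58 and 1.58. Regions farther from the starts of Trabd2b, of the cathepsin gene Ctsz and of Smad4, the shared SMAD of TGF-beta and BMP signalling, had 1.94, 1.61 and 1.58. The lowest ratios were at a region 3085 bp from the start of the mucin gene Muc3 (31 and 2, log2 ratio -3.42) and the promoter of Sdc2, which encodes the cell-surface proteoglycan syndecan-2 (29 and 3, log2 ratio -2.91). The Asmt promoter, on chromosome X (170672909 to 170673543), held 208 and 29, a 7.17-fold difference (4.80 to 11.1). In the knockout 8 of 9 regions on chromosome Y were also lower. Whether the Asmt difference goes with a difference of the sex chromosomes between the cultures was not tested. The Brox promoter held 404 and 79, a 5.11-fold difference (3.98 to 6.64). The Brox log2 ratio of -2.34 became -1.49 after quantile and -1.47 after loess scaling. Promoters of Zfp2, Tmem123, Ccpg1, Sucla2, Smim7 and Commd3 had log2 ratios between -2.54 and -2.32.

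Of the 599 listed genes, 73 had a region in the Kindlin-2 table, and each list is described over those with a promoter region. In the integrin adhesion list 10 of 38 genes were measured, 3 were higher (Fermt1, Itgb8 and Actn1) and 0 lower, and the other 7, among them Zyx (log2 ratio -0.44), Vcl (-0.36) and Ilk (0.00), lay within 2-fold. The list's median of -0.18 stood at the 63.1st percentile of matched random lists. Itgb8 and Actn1 lie on chromosome 12, whose regions had a median of 0.55, and both were under 2-fold once each chromosome was centred (log2 ratios 0.993 and 0.742). When centred on neighbouring regions, Itgb8 just passed (1.002) and Actn1 did not (0.968). Of 4 YAP and TEAD targets, 3 were lower, including the phosphatase gene Ptpn14 (33 and 16). By promoters this list was too small for a percentile. With all regions of 5 such genes the median was -1 on the log2 scale, at percentile 0.955, the 1 of 8 lists by all regions in the lowest 2.5% of random lists, against 0 of 7 lists by promoters. It lay between -1.26 and -1 under the other scalings, although Ptpn14 was within 2-fold after quantile or loess scaling. In the TGF-beta and myofibroblast list, 2 of 6 promoters were higher and 1 lower. These were Snai1, a repressor of epithelial genes (1 and 13, ratio 13 with an interval of 1.44 to 406), Tgfbr2 (0 and 8, at least 1.96-fold higher against the floor, exact lower limit 1.25) and Skil, a SMAD corepressor, which was 2.21-fold lower. Loess scaling brought all 3 within 2-fold and turned the sign of Tgfbr2. Among 9 cell cycle genes, Ccne2 and Ccna2, cyclins of S phase, were 2.4-fold and 2.29-fold lower and E2f1 was 2.29-fold higher, with an interval that reached below 1 for E2f1 (0.823 to 8.21). All 3 were within 2-fold after loess scaling but kept their direction (log2 ratios -0.94 for Ccne2, -0.81 for Ccna2 and 0.91 for E2f1).

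In the smaller groups, 1 of 7 NF-kB targets was lower at its promoter, Birc2 (42 and 17), which encodes an inhibitor of apoptosis, and a region 4827 bp from the start of Il1rn was 2.38-fold lower. Of 3 extracellular matrix genes, Thbs1 was 2.5-fold higher and Fn1, the fibronectin gene, 2.17-fold lower, with an interval that reached just below 1 (0.993 to 4.87). The interferon-induced Rsad2 was the 1 of 4 interferon response genes past 2-fold (1 and 13, interval 1.44 to 406). After loess scaling Rsad2 (0.97), Il1rn (-0.98), Fn1 (-0.97), Mkl2 (0.21), Kdm1a (0.47) and Tfrc (-0.01) were within 2-fold, and Birc2 (-0.84) was so with chromosomes centred. Among 5 measured genes of the SRF and MRTF list, Mkl2 was higher, an MRTF gene itself rather than a target. Tfrc was higher among 5 housekeeping genes. Each rose from a signal under 5 and had an interval reaching below 1. None of 6 histone methylation enzymes, 4 Wnt signalling genes and 2 AP-1 factors passed at a promoter, and a region 4038 bp from the start of Kdm1a held 5 and 12, with an interval that also reached below 1 (0.668 to 9.38). Of the markers of other cell types, 2 of 27 epithelial genes had a promoter region, both within 2-fold, and a region of the leukocyte gene Ptprc was 2.7-fold higher. The fibroblast, endothelial, pericyte and smooth muscle, adipocyte, skeletal muscle, chondrocyte and osteoblast, neural and heart marker lists and the Hox list had 0 measured genes here.

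Promoters made up 46.6% of all regions, 26.2% of those higher in the knockout and 53.1% of those lower, with odds ratios of 0.346 and 1.33. Of the 925 higher regions, 632 had no assigned gene. The direction followed the signal level: the median log2 ratio was 0.70 in the weakest of 4 equal groups of regions by signal, with 570 higher and 54 lower, and -0.35 in the strongest group, with 40 higher and 218 lower. Chromosome medians ran from -0.42 on chromosome 9 to 0.55 on chromosome 12, apart from -1.82 over 9 regions of chromosome Y and -1.09 over 2 mitochondrial regions. No test was possible. With equal levels and counting error alone, draws gave on average 320 higher and 240 lower regions with a knockout factor of 1, and 265 and 96.1 with the weakly fitted one. Only 61 higher and 87 lower regions had a counting interval wholly beyond 2-fold. Higher regions were 63.5% of those past 2-fold as deposited, 47.1% after loess scaling (457 higher, 513 lower), 48.7% after quantile scaling (573 and 603) and 30.1% among regions of at least median signal (166 and 385).

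**Figure D1:**
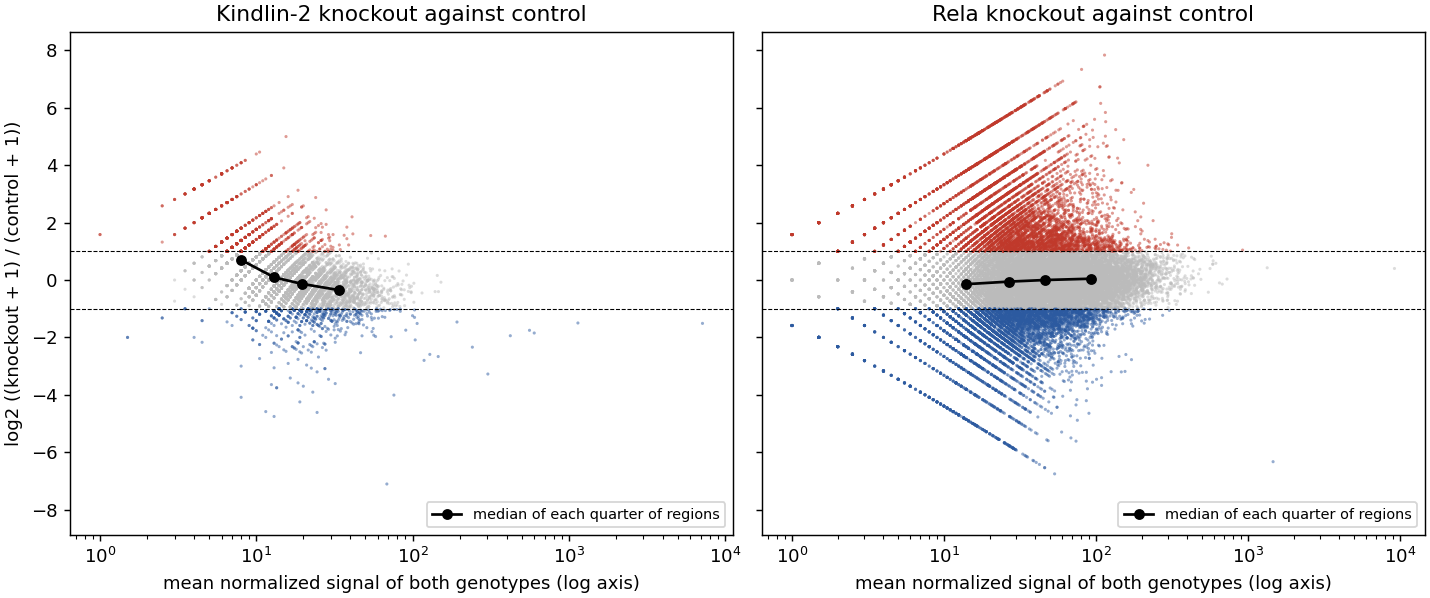
Log2 ratio of knockout to control (vertical axis, pseudocount 1) against the mean normalized signal of both genotypes (log axis) for each nuclear region of the Kindlin-2 table (left) and the Rela table (right). Red regions were at least 2-fold higher and blue ones at least 2-fold lower in the knockout, and black points join the medians of 4 equal groups of regions by signal, which run from 0.70 to -0.35 for Kindlin-2 and from -0.14 to 0.05 for Rela.

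The second comparison asked how accessibility differs between Rela knockout and wild-type 3T3 fibroblasts. Promoters of several NF-kB targets were lower without Rela: the chemokine genes Ccl7 (20 and 1, ratio 20 with an interval of 3.46 to 852) and Cxcl10 (4.5-fold, 2.26 to 9.07), and the collagenase gene Mmp13 (10.8-fold, 4.21 to 42.9). The promoter of Mmp3, encoding the matrix protease stromelysin-1, was 18.7-fold lower (56 and 3, 6.50 to 97.4). Mmp13 and Mmp3 lie near each other on chromosome 9 (starts 7272258 and 7445610), so they may not be separate differences. The list as a whole did not stand apart: of 24 measured NF-kB targets 4 were lower, 2 (Tlr2 and Csf1) higher and 18 within 2-fold, with a median of -0.17 at the 21st percentile of random lists. The promoter of the T-box gene Tbx3 held 1 and 140, and that of the homeobox gene Msx1 held 54 and 1. Of 28332 regions, 6340 were at least 2-fold higher and 5939 at least 2-fold lower in the knockout.

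The 1 region assigned to Rela, at its promoter on chromosome 19 (5637247 to 5637615, 52 bp from the start), had a signal of 21 in wild-type and 27 in knockout cells, a ratio of 1.29 (0.725 to 2.16). A promoter region does not check a deletion elsewhere in the gene. Among regions with a gene symbol and at least median signal, the highest ratio was at the promoter of the Eph receptor gene Ephb6 (1 and 211, log2 ratio 6.73). Promoters of Sorcs1 and of Pctp, a phosphatidylcholine transfer protein gene, and a region of Isoc2b had a signal of 0 in wild-type cells and were at least 38.1-fold, 36.6-fold and 37.6-fold higher against the floor, with exact lower limits of 30.2, 29.1 and 29.8. Olfr654, Tbx3, the cadherin gene Cdh6 and Cdyl2 at promoters, and Paqr8 and Pax9 at 4640 and 3990 bp from their starts, had log2 ratios from 5.60 to 6.17. On the same terms the lowest ratio was at a promoter of Dmd, the dystrophin gene, with 85 in wild-type and 0 in knockout cells (at least 29.9-fold lower against the floor, exact lower limit 23.8). A region 7941 bp wide on chromosome 8 (123426192 to 123434133), assigned to Def8 but 6636 bp from its start, held 2897 in wild-type and 35 in knockout cells, an 82.8-fold difference (59.8 to 117). It was among the strongest regions of the Rela pair, and the sequence it covers was not analysed. Regions without an assigned gene, named outside the rule for their extreme ratios, went further. The region on chromosome 1 (170942205 to 170947167) held 1349 and 4 (log2 ratio -8.08). Another, on chromosome 18 (69415531 to 69416022), held 0 and 161, at least 78.6-fold higher against the floor (exact lower limit 63.3). Osbp, Phf11, Inmt, Zfp972, Crisp2, Rragb, Frk and Birc6 followed with log2 ratios between -4.77 and -3.15.

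In the extracellular matrix list 27 of 49 genes had a promoter region, 5 higher and 6 lower. Besides Mmp3 and Mmp13, the tenascin gene Tnc was 3.68-fold lower, while the thrombospondin gene Thbs2 was higher (3 and 11, ratio 3.67, interval 1.26 to 17.7). Among promoter lists of at least 5 genes the Hox list stood lowest, with a median of -1.10 at percentile 1.47 over 6 of 39 genes: Hoxa3, Hoxd13 and Hoxa10 were 5.9-fold, 5.11-fold and 3.44-fold lower, and Hoxb9 was higher (1 and 10, ratio 10, interval 2.22 to 658). Its median stayed between -1.30 and -0.93 over the alternatives tried. Hoxa3 and Hoxa10 lie close together on chromosome 6 (starts 52212897 and 52240440), and the random lists were not matched on position. The Hox percentile may therefore overstate how far the list stands apart. In the TGF-beta and myofibroblast list 3 of 25 promoters were lower and 0 higher, namely Smad3, a transducer of TGF-beta (4.91-fold), the ligand gene Tgfb2 (3.56-fold) and Tgfbi (2.78-fold). Of 25 cell cycle genes 6 were lower and 1 higher. The retinoblastoma gene Rb1 was 5.89-fold lower (3.12 to 14.1), and Cdk1, E2f3 and the p53 antagonist Mdm2 were 3.25-fold, 2.75-fold and 2.69-fold lower. The medians of these 3 lists, 0.20 for the matrix, -0.16 for TGF-beta and -0.13 for the cell cycle, lay within the central 95% of random lists, and that of the matrix list was -0.06 over all regions of its genes. Cell cycle genes Cdk1 and Mdm2 lie on chromosome 10 and E2f3 on chromosome 13, whose medians were -0.58 and -0.79. With chromosomes centred, E2f3, Mdm2 and Tgfbi were within 2-fold.

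Of 9 AP-1 factors, the stress-induced Atf3 (6.9-fold for 1 of its regions) and Fos (2.54-fold) were lower and Jund was 2.17-fold higher. One of the 3 Mafk regions was 3.13-fold lower. In the interferon response list 3 of 12 promoters were higher, the antiviral genes Mx1 (2.91-fold), Gbp3 (2.65-fold) and Bst2 (2.07-fold), and Cxcl10 was lower. The interferon median was -0.52, at percentile 5.50, and -0.09 once chromosomes were centred. That centring also brought Gbp3 (0.82), Bst2 (0.42), Jund (0.50), Gadd45b (-0.69), Tlr2 (0.98), S100a4 (0.98), Krt19 (0.96), Cdh16 (0.81) and Msx2 (-0.74) within 2-fold, and centring on neighbouring regions did so for Mx1 (0.92), Egr2 (-0.98), Cald1 (-0.56), Kdm3a (0.73), Dpt (-0.74), and Kdm1a (-0.66) and Col1a2 (-0.49) away from promoters. Kdm1a was also within 2-fold after loess scaling (-0.92). Other named regions kept a 2-fold difference when centred on neighbouring regions but with a ratio over 1.5 times smaller: Rb1 (log2 ratio -2.43 to -1.56), Itga1 (-2.26 to -1.35), Tgfb2 (-1.77 to -1.16), Dot1l (-1.95 to -1.17), Pax3 (2.58 to 1.87), Sfrp1 (4.36 to 3.61), Isoc2b (6.29 to 5.39), Paqr8 (6.16 to 5.45), Cdyl2 (5.66 to 4.97), Phf11 (-4.17 to -3.53), Frk (-3.25 to -2.55) and Birc6 (-3.15 to -2.52). Among 10 Wnt signalling genes the antagonist Sfrp1 (1 and 40, ratio 40, interval 9.92 to 2359) and the receptor gene Lgr5 (0 and 11, at least 5.37-fold against the floor, exact lower limit 3.86) were higher. Of 16 YAP and TEAD targets 5 were lower and 1 higher, with 1 region of Ptpn14 4.67-fold lower and Ankrd1 2.59-fold higher. Integrin genes Itga1 and Itga7 were 4.9-fold and 4.67-fold lower and the paxillin gene Pxn was higher (3 and 10) among 15 integrin adhesion genes. Of 22 SRF and MRTF targets 3 were lower, Egr2, Fos and Cald1. By promoters, Kdm3a (64 and 143) was the 1 of 14 histone methylation enzymes past 2-fold and Rplp0 (34 and 11) the 1 of 17 housekeeping genes. Away from promoters, regions of Dot1l (26 and 6) and Kdm1a (31 and 15) were lower and a region of Tet2 (11 and 36) was higher.

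Markers of other cell types were mostly unmeasured, and those with regions differed both ways. Of 7 fibroblast markers S100a4 and Fbln1 were higher and Dpt lower. The epithelial genes Krt19 and Cdh16 were higher at promoters and Pkhd1 lower, and over all regions of 5 epithelial genes, with Krt7 and Pax8 also lower, the median was -1.53 at percentile 0.175; the interval of Cdh16, with signals of 2 and 7, reached below 1. Higher promoters were those of Laptm5 (8 and 46) among 3 immune markers and Pax3 (3 and 23) for skeletal muscle. Sox2 (9 and 63) among 3 neural markers and Tbx20 (1 and 47) for heart were also higher. Among 4 adipocyte markers, Ebf2 (3 and 34) and Cebpa (22 and 66) were higher at promoters and Fabp4 was lower (16 and 5). Over all regions of each gene, 0 of the 4 adipocyte markers were lower. Away from promoters, the heart marker Myl7 (14 and 2) and the fibroblast marker Col1a2 (40 and 18) were lower. Msx1 and Msx2 (48 and 16) were lower among 3 chondrocyte and osteoblast markers. The endothelial marker Sox18 was lower at a region away from its promoter (33 and 6). None of 3 pericyte and smooth muscle markers passed at a promoter. Of the lists large enough for a percentile, 1 of 14 by promoters (Hox) and 2 of 16 by all regions (Hox and epithelial) lay in the lowest 2.5% of random lists, and 0 in the highest.

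**Figure D2:**
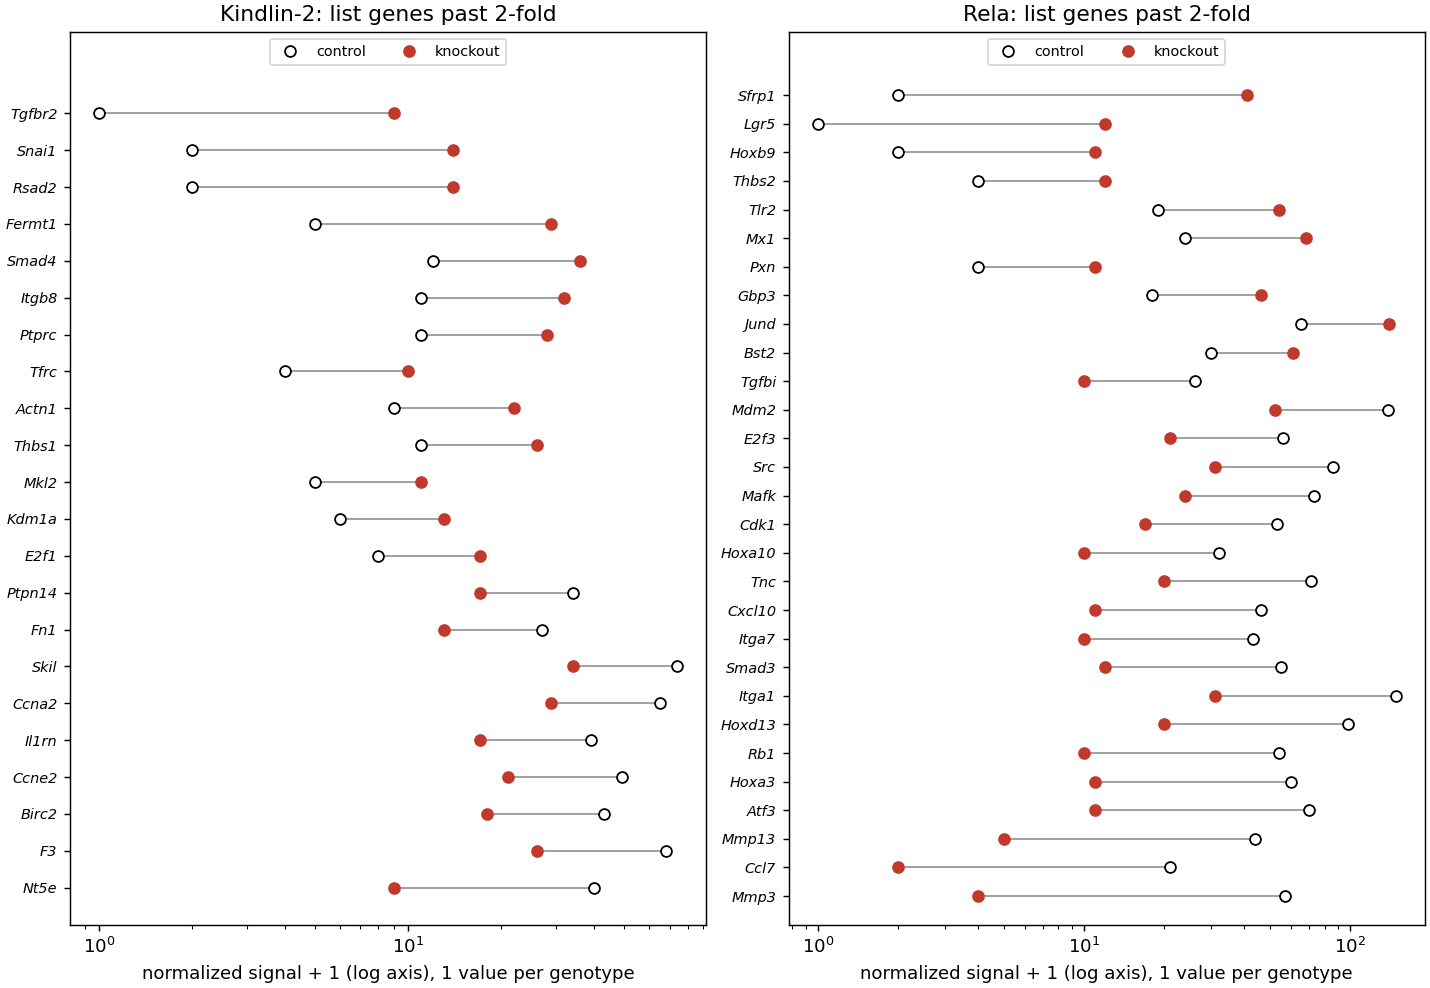
Normalized signal plus 1 (log axis) in control (open points) and knockout cells (red points), 1 value per genotype. Shown are the named list genes, up to 4 per list, with a region at least 2-fold apart. All lists were used for Kindlin-2 (left) and 9 pathway lists for Rela (right). A gene in more than 1 list was kept under the first alone, so Fos and Tgfb2 are missing on the right. Fermt1 runs from 4 to 28 in the Kindlin-2 pair, and Mmp3 from 56 to 3 in the Rela pair, before 1 is added.

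Promoters were 28.5% of Rela regions and had the fewest differences: 26.1% of them passed 2-fold, against 51.0% of regions without an assigned gene. Promoters also had the stronger signal, with a median of 52.5 against 30.5, and differences were fewer at strong regions, with 870 higher and 626 lower of 7083 in the strongest of 4 equal groups by signal, and 2048 and 2239 in the weakest. They made up 16.5% of the higher and 17.8% of the lower regions (odds ratios 0.422 and 0.474). The direction also differed by chromosome. On chromosomes 8 and 3 the medians were 0.61 and 0.53, and 727 and 642 regions were higher against 195 and 224 lower. On chromosomes 13, 10 and 17 they were -0.79, -0.58 and -0.56, and 546, 531 and 435 regions were lower. No test was possible. Counting error alone gave on average 315 higher and 351 lower regions, and 3666 higher and 2470 lower regions had a counting interval wholly beyond 2-fold.

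**Figure D3:**
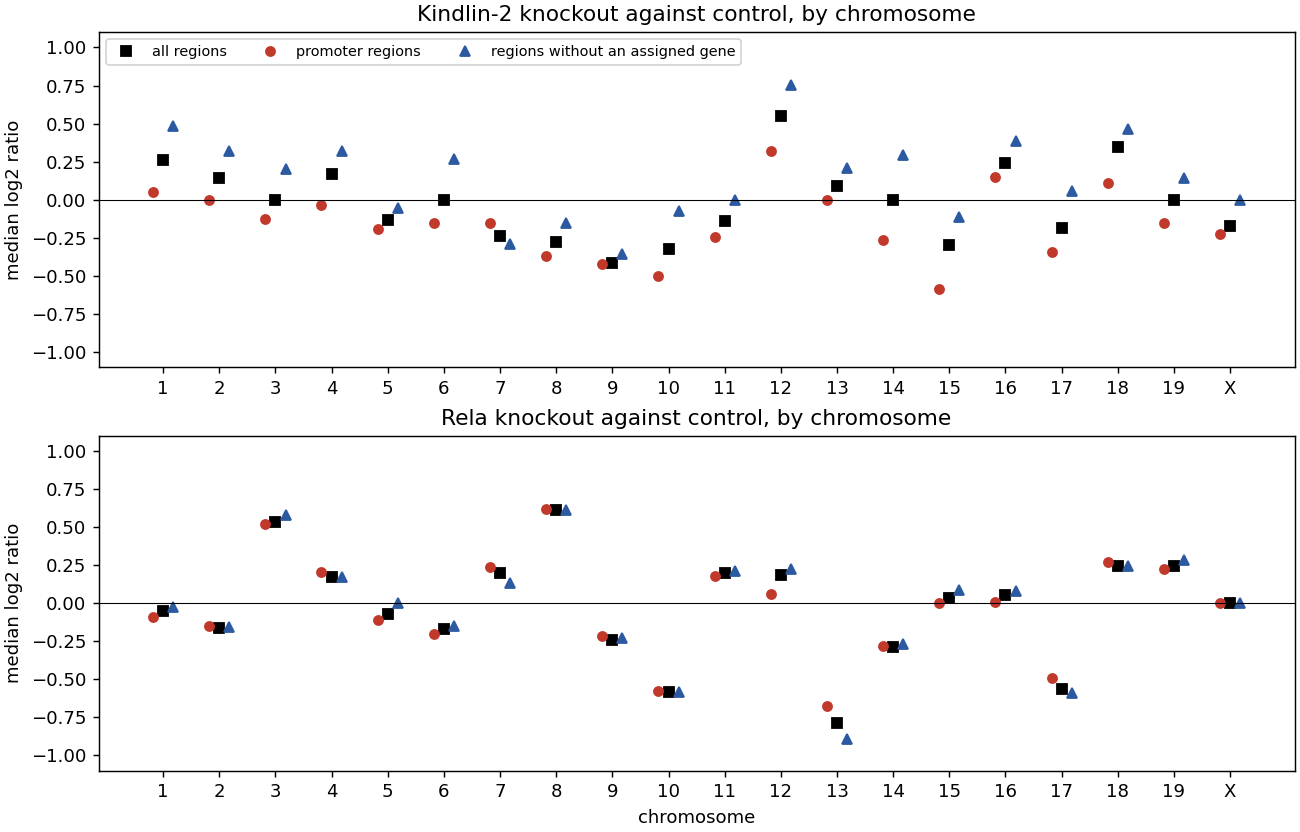
Median log2 ratio of knockout to control (vertical axis) on each chromosome (horizontal axis) for all regions (squares), promoter regions (circles) and regions without an assigned gene (triangles), in the Kindlin-2 table (top) and the Rela table (bottom). For Rela the 3 medians lie close together, from -0.79 on chromosome 13 to 0.61 on chromosome 8 over all regions, and for Kindlin-2 promoters lie below unassigned regions on each chromosome that has both except chromosome 7.

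The third comparison asked whether the same regions differed in both knockouts. Of the Kindlin-2 regions, 4583 overlapped a Rela region. Among these, 99 were higher in both knockouts, where independent lists would share 62.5, and 39 were lower in both, where 46.6 would be shared. Kindlin-2 higher with Rela lower held 78 regions against 53.1 for independent lists, so regions higher in the Kindlin-2 knockout were more frequent than that among Rela regions differing in either direction. The correlation of the log2 ratios across regions, which are not independent replicates, was 0.00599 (Spearman). Among regions of at least median signal in both tables, 10 were higher and 24 lower in both, against 7.91 and 23.3. Regions higher in both included those of Pax9 (12 and 25 with Kindlin-2, 3 and 193 with Rela), Cldn23 and Bach1. Those lower in both included Muc3 (31 and 2, 16 and 2), the cell cycle gene E2f7 and Map3k14, which encodes the NF-kB-inducing kinase. These shared genes were chosen after their values were seen. Pax9 had a Kindlin-2 log2 ratio of 1 and lies on chromosome 12, whose Kindlin-2 median was 0.55. Its Kindlin-2 ratio was therefore within 2-fold once chromosomes were centred. E2f7 had log2 ratios of -1 with Kindlin-2 and -1.03 with Rela. It lies on chromosome 10, with medians of -0.32 and -0.58, and was within 2-fold in both pairs once chromosomes were centred.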

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

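For the numbers of higher and lower regions, the alternatives chosen after seeing the data were centring on neighbouring regions, leaving out mitochondrial, Y and wide regions, and a counting interval wholly beyond 2-fold. All scalings of list medians, promoter shares and shared regions were also chosen then. No paired analysis was possible because the results come from no test, with 1 column per genotype.

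In the Kindlin-2 comparison, with 925 higher and 531 lower regions, a pseudocount of 5 gave 543 higher and 335 lower, and regions of at least median signal gave 166 higher. Quantile scaling gave 573 higher and loess scaling 457. The counting interval lay wholly beyond 2-fold for 61 higher and 87 lower regions. Promoters within 1000 bp were 22.8% of the higher regions. In the Rela comparison, regions of at least median signal gave 2380 higher and 1931 lower, and the counting interval lay wholly beyond 2-fold for 3666 and 2470. Promoters within 1000 bp were 11.9% of higher and 12.5% of lower regions. Regions higher and lower in both knockouts numbered 10 and 24 (chance 7.91 and 23.3) at or above the median signal. Loess scaling left 48 higher in both (chance 34.1), and chromosome centring left 21 lower in both (chance 33.9). A larger pseudocount, a filter, an interval and a shorter distance admit fewer regions by construction; for the scalings the cause was not tested.

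Of the list medians, 1 moved beyond its spread for Kindlin-2, while 14 planned and 27 added values did not, and 3 moved for Rela, while 27 planned and 54 added values did not. They were TGF-beta and myofibroblast in Kindlin-2 (-0.25, chromosomes centred), extracellular matrix (-0.06, all regions), SRF and MRTF targets (-0.11, loess) and interferon response (-0.09, chromosomes centred). Medians near 0 changed sign without moving beyond their spread, such as integrin adhesion in Kindlin-2 (0.03 after loess). After loess scaling the called promoters of Tgfbr2 (3.17 to -0.15) and Tfrc (1.32 to -0.01) in Kindlin-2 changed sign and were within 2-fold. The balance of Kindlin-2 regions also turned, to 513 lower after loess, 603 lower after quantile scaling and 385 lower at or above median signal, each more than the higher ones. Median-of-ratios scaling and a smaller pseudocount changed no call, because the median ratio was already 1 and the values are whole numbers. The filter on low values removed no Kindlin-2 region. Moderated tests, replicate blocks, leaving out a replicate, set tests with estimated correlation and motif backgrounds were not run, since they need replicate columns or the genome. Depth limits the precision of the Kindlin-2 pair, with a median of 11.8 implied counts in floxed cells.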

Other observations

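The tests below were written down before their values were seen, but the patterns they weigh, the regions named and the pathway medians were chosen after seeing the data.

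Among Rela-pair regions, 772 had a signal of at least 35 in 1 genotype and at most 3 implied counts in the other, 487 with signal in the knockout alone and 285 in the wild type alone. Promoters with signal in the knockout alone, named here as single genes with no test of any group, included Tbx3 (1 and 140), Tbx20 (1 and 47), Pbx3 (2 and 44), Dmrta2 (2 and 38), Sox12 (2 and 87), Rorb (1 and 87), the cadherin genes Cdh6 (1 and 123) and Cdh10 (0 and 40), the Eph receptor genes Ephb6 (1 and 211) and Epha5 (0 and 61), the thrombomodulin gene Thbd (1 and 71) and Cd34 (1 and 42). Promoters with signal in the wild type alone included those of Dmd (85 and 0), the homeobox gene Msx1 (54 and 1), the protease gene Mmp3 (56 and 3), Xdh (46 and 2) and the carboxypeptidase gene Cpa4 (55 and 3). Promoters were 60 of the 487 and 32 of the 285 regions.

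Over 243 KEGG pathways with at least 10 Rela-pair promoter genes, 3 medians fell in the lowest 2.5% of random lists and 5 in the highest, where chance gives 6.08 on each side. Lysine degradation had the lowest percentile (0.51, median -0.38), with 1 of 28 genes higher and 2 lower, while arachidonic acid metabolism had a lower median (-0.72) at percentile 1.73, and olfactory transduction had the highest percentile (99.3), with 6 of 17 genes higher and 3 lower. With chromosomes centred, olfactory transduction (96.5) and arachidonic acid metabolism (6.63) left the outermost 2.5%, and 2 pathways on each side lay there under both settings. In the Kindlin-2 table, 8 of 9 regions on chromosome Y were lower in the knockout, and the region from 259094 to 259422 held 137 and 0, at least 45.7-fold lower against the floor (exact lower limit 36.6). The Y regions starting at 142906 (16 and 0) and 11858087 (26 and 0) also fell to 0. Those starting at 90739902 and beyond kept a knockout signal of 3 to 26. Whether the 2 cultures differ on chromosome Y apart from Kindlin-2 was not tested.

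The 772 on-off regions of the Rela pair were weighed first. The same selection over all regions of 100 draws with counting error alone gave at most 0 such regions. So strict a definition leaves little room for counting error, and the draws argue against that cause alone, not against differences between cultures or replicates. Deletion of longer stretches stays open. Of 532 such regions with a neighbour within 50 kb, 20.3% had that neighbour also without signal in the same genotype. This was just above the 20% under which deletion was to be set aside. Over all regions, 9.24% were without signal in at least 1 of the 2 genotypes. That counts either genotype, so the share of all regions without signal in a given genotype was at most this, below the 20.3%. All regions were not matched to these neighbours in position or signal. The gap therefore does not decide for deletion. Each genotype had 1 column of values, and the number of cultures or lines behind it is not stated. The loss of Rela and other differences between the cultures therefore cannot be told apart.

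Rela-pair ratios shifted by chromosome, with medians spanning 1.40 on the log2 scale. Shuffling single regions over chromosomes gave a range of at most 0.242, which argues against a chance spread of independent regions. Differences shared by neighbouring regions are broken up by the shuffle, so it cannot weigh them. Promoter and unassigned medians followed each other over 20 chromosomes (Pearson r 0.978, Spearman 0.967, and 0.974 without the 2 farthest). A different copy number of chromosomes in the 2 cultures would give this, and so would any other shift of whole chromosomes. Copy number itself was not measured, and a biological difference between genotypes was not tested.

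Kindlin-2 ratios ran from positive at weak to negative at strong regions, with a difference of -1.05 between the medians of the strongest and the weakest of 4 equal groups by signal. Counting error reached -0.19 at most in 100 draws with a knockout factor of 1 and -0.23 with the weakly fitted one, which argues against it as the whole cause. The trend was -0.75 within promoters, so a different behaviour of promoters and other regions is not the whole of it either. The authors' normalization, a lower enrichment of open chromatin in the knockout library and the genotype itself stay open and were not tested.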
